A study of Mus musculus with 20 samples.

How the data were processed

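Total RNA from the livers of 20 mice, 10 HFD and 10 MSXH, was labelled with biotin and put on Affymetrix 3' arrays, 1 array per mouse, per the labels. The deposited values are taken as log2 levels of probe sets: their range, 5.17 to 15.01, with no missing or negative value, is that of log2 scanner intensities, but the base is not stated. The scanner software, background correction, normalization and summarization are not given in the sources used here. The 20 columns have nearly the same distribution, and the spread of a probe set between arrays is strongly compressed (44 of 45101 probe sets had an SD above 0.1), so that no difference was read as a fold of RNA and values were not changed before the test. For arrays, the number of mice limits the precision.

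Probe sets were joined to genes with the platform's gene table: 34958 had 1 symbol, 932 had several and 9211 were not listed, and 64 are controls. Gene IDs of 34754 were found in the GRCm38.p6 gene table, which changed 0 symbols. Control probe sets and those without exactly 1 symbol were left out. Of the 9010 genes with several probe sets, the probe set with the highest mean over all arrays was used, which left 18193 genes, with no filter on level. Groups were taken from the sample titles, and the replicate numbers only name mice: in a check, the correlation of mice that share a number ran from -0.265 to 0.165, so no pairs were modelled.

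The main test was limma 3.58.1 in R 4.3.3, with lmFit on the 2 groups and eBayes with a trend of variance on level (18 residual and 0.704 prior degrees of freedom), two-sided, with the Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. A standardized difference is the difference of group means over the pooled SD within groups, with a noncentral t interval at 95%. A gene's share of pairs is the number of the 100 pairs of an MSXH and an HFD mouse in which the MSXH mouse was higher.

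The 35 lists, the tests, the rule for named genes and the alternatives listed first below were set before the data were examined. Each list was tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation, with fry, and as a level per array in a two-sided permutation test with 100000 permutations, each with Benjamini-Hochberg over the lists. Camera sets a list against all other genes. A list that camera placed higher or lower, or that turned under a scaling, did so relative to them, whichever way its own members moved. Lists needed 5 measured members, which all of them had. The lists cover lipid, glucose, bile acid and amino acid metabolism, detoxification, stress, immune and clock genes, complexes, and markers of the cell types a liver sample could hold. The rule for named genes took the genes past the threshold or, with fewer than 24, the genes of smallest p up to 24 (described as not past it), the 4 members of smallest p of each list called, and the 1 member of smallest p of every other list. This gave 72 genes. Eno3, Tor4a, Tnfrsf22, Mt1, Cyp17a1, Hsd3b5, Adipoq, Fabp4, Cryab, Lpl and the muscle genes fall outside the rule and were chosen after their values were seen.

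Alternatives set in advance were quantile normalization, array centring, genes above the median gene, a block by replicate number, the mean of a gene's probe sets, all probe sets, eBayes without trend and with a robust trend, array weights, the rank sum test, the rank product, an adjusted p of 0.10, a fold of 1.2, and leaving out each array. Added after seeing the data were leaving out MSXH 4 and 6, alone, with either scaling and with an estimated correlation, a t test without empirical Bayes, the most variable probe set of a gene, the standardized list level, and other nulls for the rank product. The first null of the rank product, which shuffles each pair's differences, called 6283 unchanged genes when tested on simulated data and was replaced by one that shuffles the values of each array.

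The tests were run on simulated data of 18193 genes and 10 mice per group. Genes were shifted together in 1 run, 50 at each of 1, 1.5, 2 and 3 SD, with noise drawn independently for each gene. Of these, limma recovered 14% at a shift of 1 SD, 18% at 1.5 SD, 34% at 2 SD and 96% at 3 SD. Over the whole run 4 unchanged genes were called. For lists of uncorrelated genes shifted by 0.6 SD, camera recovered 5 of 5 with 0 others called. At a correlation of 0.3 between members, camera at the preset correlation called 5 of 5 and 9 unchanged lists, with an estimated correlation 4 of 5 and 4 unchanged lists, and fry and the standardized level called 0. Group comparisons were also repeated on 100 splits of the arrays. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the rank products and the figures.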

Results

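Liver RNA of 20 male C57BL/6J mice, 8 weeks old and fasted for 16 h, was measured on Affymetrix 3' expression arrays, with 1 array per mouse. For 4 weeks, 10 mice had eaten a diet with 45 kcal% fat (HFD), and 10 had eaten that diet with 0.02% of the extract that the labels name MSXH, from maple syrup. The low-fat group and the group with a higher share of extract that the series text names were not analysed here. Each array gave 45101 values on a log scale between 5.17 and 15.01, with array medians between 6.5216 and 6.5226. The number of arrays limits the precision. The spread between arrays was compressed: the median probe set had an SD of 1.07e-05 over the 20 arrays, and 97.6% of the probe sets had an SD under 0.001. Differences between groups are therefore given as standardized differences (MSXH minus HFD, divided by the pooled SD within groups, 10 mice against 10) with their 95% confidence intervals, and not as folds.

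The comparison of MSXH with HFD asks what the extract did to the liver of mice on the high-fat diet. Prokr1, a G protein-coupled receptor for prokineticins, had the smallest p of the 18193 genes and was lower in MSXH in every pair of an MSXH and an HFD mouse, with a standardized difference of -2.75 (interval -3.98 to -1.48). Aspg, an asparaginase, was higher in 100 of the 100 pairs, with a difference of 2.63 (1.39 to 3.83), but lower after quantile normalization. The zinc finger gene Zfp467 was higher by 2.46 (1.26 to 3.63) and in 97 of 100 pairs. Mid1ip1, whose protein binds acetyl-CoA carboxylase in fatty acid synthesis, was higher by 2.31 (1.14 to 3.44) and in 98 of 100 pairs. Fut2, a fucosyltransferase, was lower by a standardized difference of -2.76 (-3.99 to -1.49) and was the higher one in MSXH in 2 of 100 pairs. None of these genes passed an adjusted p of 0.05. Prokr1 and Fut2 lay under every array median, at mean levels of 6.499 and 6.369, with group differences of -1.08e-05 and -4.07e-06 on the log scale. Their other probe sets stood at -0.493 and -0.623 (unadjusted limma p 0.279 and 0.176), while those of Zfp467 stood at 2.04 and 1.87. Whether Prokr1 and Fut2 were expressed was not tested.

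By limma, 0 of 18193 genes passed an adjusted p of 0.05, and 1982 had an unadjusted p under 0.05, where 909.65 would be expected by chance. The smallest adjusted p was 0.0728, shared by Prokr1, Aspg and Fam149b, and 12 genes were under 0.10, of which 7 were higher and 5 lower in MSXH. The count under 0.10 was 0 under both scalings and with the block by replicate number, and it ran from 0 to 22 when 1 array was left out. The rank sum test called 4 genes at 0.05: Aspg, Cnot6l and Eno3 higher and Prokr1 lower. The t test without the empirical Bayes step, added after the data were seen, called Cnot6l, Fut2 and Prokr1. The rank product called 5831 genes with its first null, and 1183 with a null chosen after the data were seen, which called 1063 unchanged genes on simulated values with the spreads of these genes. With a null drawn from splits of the arrays, the rank product called 0 genes. Of the genes at an unadjusted p under 0.05, 60.4% were higher in MSXH in the values as they stand, 2.27% after quantile normalization and 9.52% after each array was centred on its median. Without MSXH 4 and 6 these shares were 60.9%, 61.4% and 65.3%, in tests added after the data were seen. With all arrays and only genes above the median gene, 740 genes at that p were higher and 246 lower. The share was 75.1% there, so it depended on level.

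**Figure D1:**
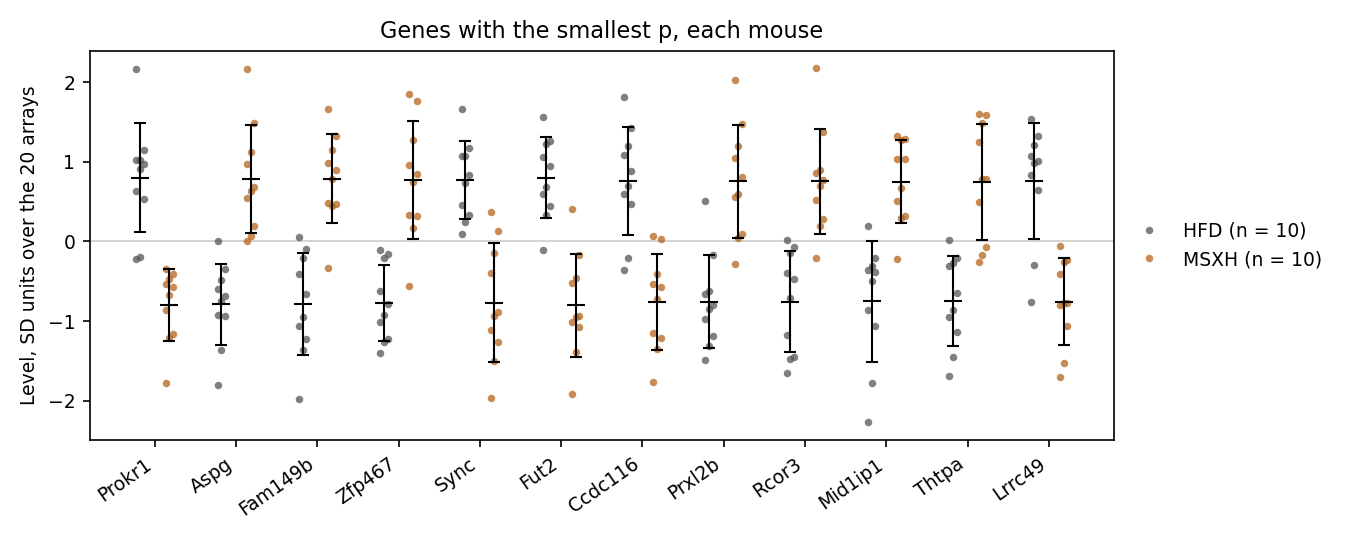
Level in each mouse (1 point per array, in SD of the gene over the 20 arrays) of the 12 genes with an adjusted p under 0.10, with the mean and SD of the 10 HFD and the 10 MSXH mice. In the values as they stand 7 genes sit higher and 5 lower in MSXH, and 4 of the 12 change direction under quantile normalization or array centring.

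Among the 24 genes of smallest p, 15 were higher and 9 lower in MSXH. Of the lower genes, Sync (6.259), Ccdc116 (6.122), Lrrc49 (5.974), Lonrf2 (6.306) and Ifitm5 (6.515) lay under every array median, as Prokr1 and Fut2 did. Of the higher genes, Stoml1 (6.434) did. Prokr1 (gene ID 58182) lies on chromosome 6, at 87578586 to 87590762 in GRCm38.p6, and Mid1ip1 (gene ID 68041) on chromosome X, at 10717365 to 10719702. Of the 15 higher genes, 11 turned under centring and 7 under quantile normalization, and of the 9 lower genes 0 did. Centring takes the array median off every gene, and the medians of MSXH 4 and MSXH 6, 6.52255 and 6.52235, lay above those of the other 18 arrays, at most 6.52172, so it lowers MSXH for all genes alike. Without these arrays, 0 of the 24 genes turned under centring, and 2 turned under quantile normalization, Pimreg and Stoml1. The directions under the scalings given for single genes here are with all arrays. Fam149b, higher by 2.62 (1.38 to 3.82), turned under both scalings. Cnot6l, a deadenylase of the CCR4-NOT complex, was higher in 100 of 100 pairs with a difference of 2.95 (1.64 to 4.23), at an adjusted p of 0.107, and turned under centring. Rnf213, a ubiquitin ligase, was higher by 2.22 in 92 of 100 pairs, Casp9, an initiator caspase, by 2.08 in 94 pairs, and Thtpa, a thiamine triphosphatase, by 2.29 in 96 pairs, and each of them turned under centring. Of these, Casp9 turned under quantile normalization too. Carhsp1 and Rcor3 were higher in 94 and 97 pairs and turned under centring alone, while Arhgap45, Plekhb2, Samd9l and Stoml1, higher in 93, 94, 91 and 93 pairs, turned under both. Other probe sets of Sync, Lrrc49, Lonrf2, Casp9, Plekhb2 and Rcor3 differed in sign from the one used, as did those of Tap1, Ehf, Rps20 and Uqcrq, which are named with their lists. Smaller differences of the same sign stood at the other probe sets of Cnot6l (0.340, 0.489 and 0.102), Rnf213 (0.395) and Carhsp1 (0.283). Those of Fam149b stood at 0.443 and 0.973 and that of Thtpa at 1.53.

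Transcripts of skeletal muscle were high in MSXH 4 and MSXH 6. Myh1, a fast myosin heavy chain, stood at 12.5 and 10.6 on these arrays and at no more than 6.03 on the other 18. Acta1, the actin of skeletal muscle, stood at 12.1 and 10.5 against at most 6.49, and Tnnc2, the fast troponin C, at 10.3 and 8.84 against at most 6.13. The mean level of 30 muscle genes, a list written after some of their values were seen, was 7.468 and 7.005 on these arrays, against 6.2510 ± 0.0086 (SD, n = 10) in HFD and 6.262 ± 0.0156 (SD, n = 8) in the other MSXH mice. The adipocyte list, in standardized units, was also highest on these arrays, at 0.709 and 1.06 against at most 0.433 on the others. Of its members, Adipoq, the adipokine adiponectin, stood at 5.836 and 5.842 against at most 5.821, and Fabp4 at 8.508 and 8.505 against at most 8.498. In other lists, the small heat shock protein gene Cryab stood at 6.99 and 6.80 against at most 6.63, and the lipase Lpl at 8.54 and 8.35 against at most 8.27. Without these arrays limma called 0 genes at an adjusted p of 0.05 and 1873 at an unadjusted p under 0.05, and 9 genes were under 0.10.

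**Figure D2:**
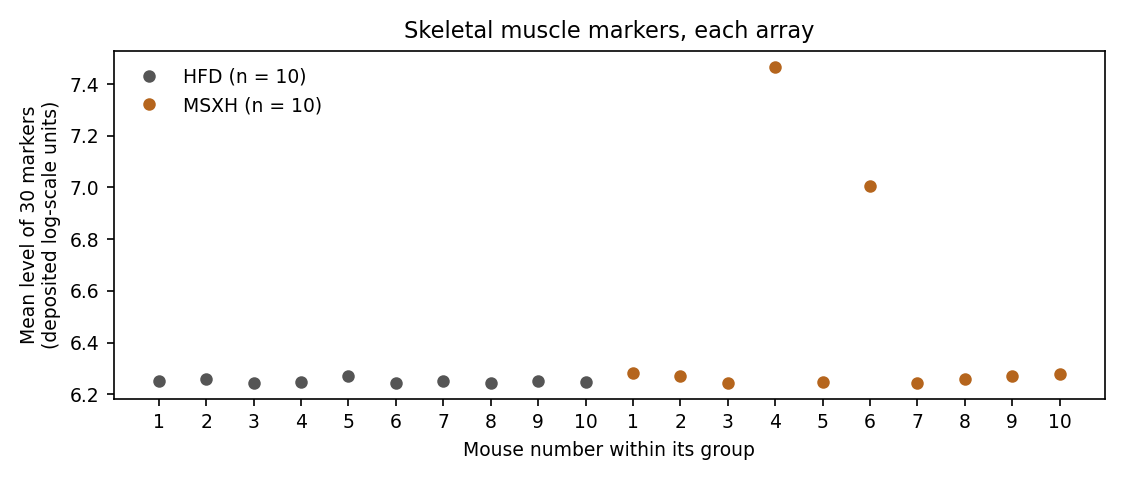
Mean level of 30 skeletal muscle genes on each array (log scale as deposited), 1 point per mouse of the HFD and MSXH groups. MSXH 4 and MSXH 6 sit at 7.468 and 7.005, and the other arrays lie between 6.24 and 6.28.

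Of 35 gene lists, camera with a preset correlation called 5. Interferon response and antigen presentation genes were higher in MSXH relative to the other genes, with 25 of 28 members higher. Relative to the other genes the list was higher under both scalings of all arrays too, as nearly all called lists were there, and without MSXH 4 and 6 under centring (1.10e-19) and quantile normalization (1.66e-04). The list had an adjusted p of 0.00226, and an adjusted p of 0.838 with an estimated correlation, and the call was lost when MSXH 9 alone was left out (0.0629). The members of smallest p were Oasl1 at 1.95, the peptide transporter Tap1 at 1.65, the transcription factor Irf1 at 1.43 and the immunoproteasome subunit Psmb9 at 1.31, of which Oasl1, Tap1 and Irf1 turned under quantile normalization and Tap1 under centring. None of the members passed over all genes, and 3 passed an adjusted p of 0.05 adjusted over the list alone: Oasl1, Tap1 and Irf1. Without MSXH 4 and 6, which carry the muscle transcripts, the list had an adjusted p of 5.82e-06, and of 0.471 with an estimated correlation. The level of the interferon list followed that of the macrophage and Kupffer cell markers, with which it shares 0 members: over the 20 mice Pearson r was 0.819 and Spearman rho 0.765 (permutation p 1e-05, the smallest possible, and 1e-04), the 1 relation of its kind computed, chosen after both lists were seen. Within HFD r was 0.692 (permutation p 0.0265) and within MSXH 0.941 (1e-05), and it was 0.745 without the 2 mice farthest from the median of the macrophage level. The macrophage list itself was higher in MSXH, with an adjusted p of 0.787, and of 0.0284 without MSXH 4 and 6, where it was 0.668 with an estimated correlation.

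Proteasome genes, which encode the subunits of the complex that degrades ubiquitinated proteins, were lower in MSXH in 25 of 31 members. Relative to the other genes the list was higher after quantile normalization, and it was not called after centring (0.0822). The call was also lost without HFD 6 and without MSXH 8 (up to 0.0785). The adjusted p was 0.00226, and 0.0166 with an estimated correlation, the 1 list called with that setting, but 65 of 100 splits of the arrays also gave at least 1 list with it. The estimate was -0.00819, against 0.405 for the ER stress list. Yet the standardized levels of both lists varied alike between mice, with SDs of 0.686 and 0.732 for proteasome and 0.583 and 0.785 for ER stress (HFD and MSXH). The estimate thus missed how far proteasome members moved together, and 0.0166 is not a stricter result. By the standardized level the proteasome permutation p was 0.266. Psma5 stood at -1.52, Psma3 at -1.41, Psma2 at -0.977 and Psmb4 at -0.736, and none of the 31 passed when adjusted over the list alone. ER stress and unfolded protein response genes were lower in 24 of 28 members, and relative to the other genes the list turned under both scalings. Its adjusted p was 0.00226, and the adjusted p was 0.838 with an estimated correlation, 0.0636 with array weights and 0.0633 without MSXH 8. Ppp1r15a, which directs the dephosphorylation of eIF2 alpha, stood at -1.21, Herpud1 at -0.903, the chaperone Dnajb9 at -0.747 and Chac1 at -0.737, and none passed when adjusted over the list alone.

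Immediate early genes were lower in 14 of 20 members, in the same direction but not called under either scaling. The adjusted p was 0.0423, 0.786 with an estimated correlation and 0.0681 with the block by replicate number. The list was called in 10 of the 20 fits that left out 1 array (0.00468 to 0.212). Gadd45g, at -1.69 and the higher one in MSXH in 10 of 100 pairs, was the 1 member to pass when adjusted over the list alone, and the transcription factors Fosb and Myc stood at -1.38 and -1.14 and the phosphatase Dusp1 at -0.850. Growth hormone and male-biased liver genes were lower in 17 of 21 members, and relative to the other genes the list turned under both scalings. The adjusted p was 0.0423, and 0.838 with an estimated correlation, 0.221 with array weights and 0.0710 with mean probe sets, and the list was called in 8 of the 20 fits that left out 1 array (0.00645 to 0.290). Cish and Socs2, inhibitors of STAT5 signalling, stood at -0.944 and -0.901 and the hydroxylase Cyp7b1 at -0.907, while Stat5a itself stood at 1.26, and at a negative value under both scalings. Without MSXH 4 and 6, the interferon, proteasome (adjusted p 4.97e-05), ER stress (0.0119) and immediate early (0.0284) lists were still called and the growth hormone list was not (0.182), and 7 lists were called in all. With an estimated correlation and without these arrays, only the proteasome list was called (0.00233, where its estimate was again near 0, at -0.00760), and the adjusted p was 0.471 for interferon, 0.512 for immediate early, 0.211 for adipocyte and 0.668 for ER stress, macrophage and PPARA genes. The others called at the preset correlation were macrophage and Kupffer cell markers, higher (0.0284), and PPARA targets and adipocyte markers, both lower (0.0383) but higher relative to the other genes under both scalings of all 20 arrays. These 2 stayed lower without MSXH 4 and 6 when centred (0.001001 and 0.00582) and under quantile normalization (0.830 and 0.197). MSXH 4 and 6 had the highest adipocyte levels of all arrays, 0.709 and 1.06 against at most 0.433. Leaving them out lowers that list in MSXH by construction, so its call there is not a separate result. With centring and without MSXH 4 and 6, all 5 lists kept their direction and their call. With quantile normalization and without these arrays, camera called 1 list, interferon (1.66e-04), and the proteasome list was higher (0.928).

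**Figure D3:**
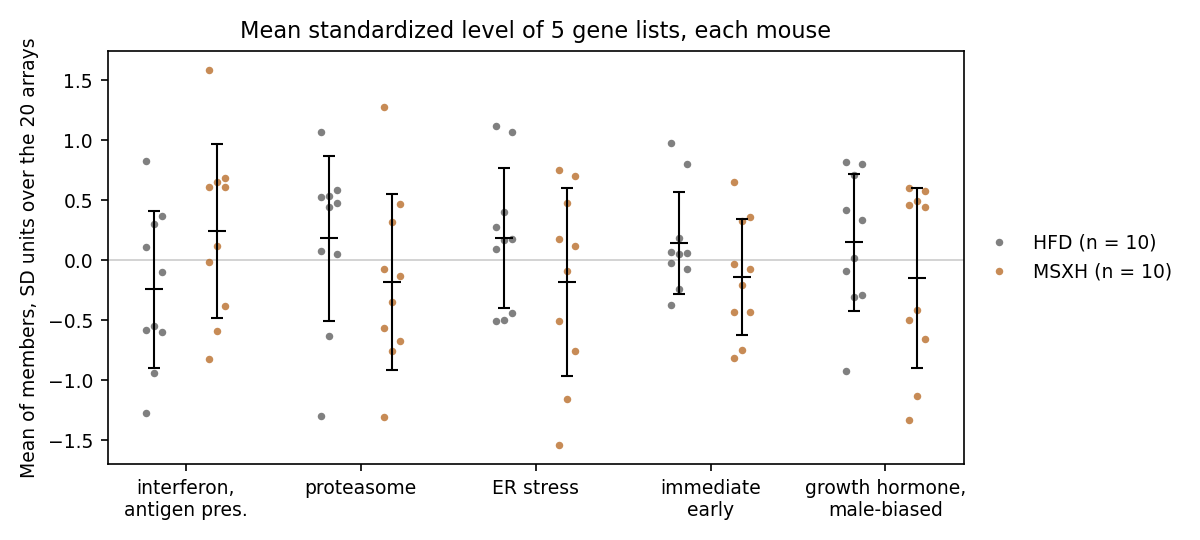
Mean standardized level of each of the 5 called lists in each mouse (1 point per array, in SD of each gene over the 20 arrays), with the mean and SD of the 10 HFD and the 10 MSXH mice. The interferon list lies higher and the other 4 lower in MSXH in the values as they stand, and in every list the 2 groups overlap. Relative to the other genes, as camera sets it, the ER stress and growth hormone lists turn under both scalings and the proteasome list under quantile normalization. The levels under the scalings are not shown.

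With the mouse as the replicate, the per-array level test called 0 of 35 lists and 2 had an unadjusted p under 0.05, the smallest adjusted p being 0.0598 for hepatocyte markers, where Cebpa made 76.2% of the summed absolute differences of the members. With each gene standardized first, it called 0 lists and 1 had an unadjusted p under 0.05. By fry, 0 lists passed in either its directional or its mixed form, and 1 had an unadjusted directional p under 0.05: fatty acid synthesis, at 0.00984 (adjusted p 0.344). Quantile normalization and centring of all arrays each led camera to call 19 lists, 18 higher and 1 lower, and 19 higher and 0 lower, against 1 higher and 4 lower in the values as they stand. These directions are relative to the other genes, while centring lowers MSXH for all genes alike.

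Camera called none of the other 30 lists, whose adjusted p values ran from 0.172 to 0.903; for each, the member of smallest unadjusted p is named with its standardized difference. Among the lipid lists, the adjusted p was 0.183 for fatty acid synthesis (Mid1ip1 at 2.31, which passed adjusted over the list alone), 0.172 for PPARA targets (Cyp4a31 at -1.02) and 0.404 for mitochondrial fatty acid oxidation (Slc25a20, the carnitine carrier, at -0.858). It was 0.787 for cholesterol synthesis (Pmvk at 0.754), 0.903 for triglyceride synthesis and lipid droplets (Cidea at 1.10), 0.903 for bile acids (the nuclear receptor Nr0b2 at 1.03) and 0.903 for lipoproteins (Angptl8 at 1.26). For glucose, it was 0.696 for gluconeogenesis (the glucagon receptor Gcgr at 1.38) and 0.593 for glycolysis and glycogen, where Gckr, the regulator of glucokinase, stood at 1.64 and passed adjusted over the list alone. For mitochondria and amino acids, it was 0.183 for the respiratory chain (Uqcrq at 1.26) and 0.787 for the urea cycle and amino acid catabolism (Haao at 1.14).

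For defence and detoxification, the adjusted p was 0.430 for xenobiotic metabolism (Ugt2b1 at -0.940), 0.540 for NRF2 targets (Gstm4 at 1.16), 0.593 for metal handling (Hjv at 1.48), 0.902 for the acute phase response (Nfkbia at -1.004) and 0.902 for heat shock genes (Hspa4l at 0.652). It was 0.803 for female-biased genes (Sult3a1 at -0.890), 0.822 for the circadian clock (Nr1d1 at 0.845), 0.787 for the cell cycle (Ccna2, cyclin A2, at -1.29) and 0.803 for ribosomal proteins (Rps20 at -1.44). Among cell type markers, it was 0.803 for hepatocytes (Cebpa at 1.58, which passed adjusted over the list alone), 0.787 for macrophages and Kupffer cells (Itgam at 1.44), 0.696 for lymphocytes (Cd3d at 1.18) and 0.903 for neutrophils (Il1r2 at 1.11). It was 0.902 for stellate cells (Timp1 at -1.02), 0.822 for endothelial cells (Pecam1 at -1.14), 0.892 for cholangiocytes (Ehf at -1.51, which passed adjusted over the list alone), 0.593 for adipocytes (Cidea at 1.10), 0.894 for acinar cells (Cel at 0.475) and 0.822 for erythroid cells (Hbb-b2 at 0.770). Camera placed the acute phase and stellate lists lower, against a positive mean and median of their members, and higher under both scalings. It placed the acinar list lower, under both scalings too, and the heat shock list lower but higher under both scalings, each against a positive mean. It placed the cholangiocyte and erythroid lists lower, but higher under both scalings, against a positive median.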

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

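The 2 tests of a shared effect of the extract on muscle genes (the limit of the second, on the size of the rise, was set when its value was known), of the 1 list called with an estimated correlation, of the lists without MSXH 4 and 6, of the parts of the list result with a component between mice, and of the markers named beside muscle were chosen only after the results were seen.

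Of 220 groups of 10 arrays, 12 held an array that stood apart from the rest, with a gap to its nearest neighbour over the group's range above Dixon's 95% critical value; this is 5.45%, and chance gives about 1 in 20. In HFD 5, Irf1 (0.484), Myc (0.622) and Gcgr (0.468) stood above the other HFD mice. In MSXH, Irf1 was high in MSXH 9 (0.566), Arhgap45 in MSXH 2 (0.498), Chac1 in MSXH 4 (0.486) and Cish in MSXH 1 (0.548). Psma3 was low in MSXH 8 (0.474) and Nr1d1 in MSXH 7 (0.501). The acinar marker level was high in MSXH 6 (0.473), the neutrophil marker level was low in HFD 6 (0.473), and the array median was low in HFD 8 (0.507). The medians of MSXH 4 (6.52255) and MSXH 6 (6.52235) stood farther from the rest, which lay between 6.52156 and 6.52172, but this measure of a single gap does not pick out 2 arrays that lie apart together.

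Skeletal muscle genes were high in MSXH 4 and MSXH 6, and muscle RNA in these samples is a candidate explanation: in a second list of muscle genes, written before its values were looked up, 18 of 27 (66.7%) had these as the 2 highest arrays, where chance gives 0.526%, and 0 of 7 heart genes did. Myh1, Acta1, Tnnc2, Mb (9.02 and 8.11 against at most 6.68) and Ttn (8.49 and 7.40 against at most 5.78) were the highest levels, and the adipocyte marker level was also highest there (0.709 and 1.06 against at most 0.433). A shift of all values of these arrays is argued against, since 1.82% of all genes had them as the highest pair. A rise of this size was not seen in the other 8 MSXH arrays. Their largest rise over the HFD mean was 4.06% of that in MSXH 6, in the deposited units. The limit of this test was set when its value was known, so it gives no verdict on an effect of the extract. A small shared rise stays open, since 3 of the 8 lay above every HFD array (permutation p = 0.0731), and so does an untested effect in these 2 mice alone. On the other 18 arrays, 12 of the 30 first-list and 11 of the 27 second-list genes lay above the median probe set, and 0 of them are in the fixed lists.

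For the 5 lists, chance cannot be excluded: 75 of 100 splits called as many, with a median of 7 and a highest of 14 in the other splits, and with an estimated correlation, which called 1 list (proteasome), 65 of 100 called as many (highest other 10). Without MSXH 4 and 6, 4 of 4 of the interferon, proteasome, ER stress and immediate early lists were called at the preset correlation, which splits often pass too. Only proteasome (0.00233) was with an estimated one. Their mean standardized differences went from 0.549 to 0.749, -0.384 to -0.525, -0.378 to -0.344 and -0.328 to -0.358. The 4 lists were put together after these calls were seen, so the count was fixed and decides nothing. The mean differences kept their sign without these arrays. In the values as they stand, the 2 arrays alone thus did not account for them. With quantile normalization as well, only interferon was called (1.66e-04) and proteasome was higher (0.928). For the growth hormone list muscle RNA stays open, since the mean standardized difference went from -0.299 ± 0.596 (SD over genes) to -0.194 ± 0.604 with 8 MSXH mice, and the call ended. A difference between mice also present within groups, taken as the first component of the genes in no list (14.8% of variance), was set in the model, and 3 of the 5 lists stayed called, between the bounds set in advance for all 5 together. The 5 were put in 2 parts after this was seen, so the counts by part were fixed and decide nothing. At the preset correlation 3 of 3 of the interferon (adjusted p 9.37e-12, but 0.115 with an estimated correlation), proteasome (1.49e-07 and 1.68e-04) and immediate early (8.49e-04, but 0.120) lists stayed called. Their mean standardized differences were 1.06, -0.674 and -0.517 with the component, so this component alone did not account for them. Of the ER stress (0.998) and growth hormone (0.916) lists 0 of 2 stayed called, as mean differences went from -0.378 ± 0.339 to 0.0174 ± 0.447 and from -0.299 ± 0.596 to 0.178 ± 0.667. The component itself stood at -0.320 ± 0.736 in HFD and 0.320 ± 1.16 in MSXH (SD, n = 10 each, permutation p 0.155). Within HFD and MSXH, r with it was -0.643 and -0.747 for the interferon level. It was -0.530 and -0.882 for ER stress and 0.499 and 0.415 for proteasome. Setting it in the model thus also moves the group difference, and these fits do not separate the 2. Other differences between mice stay open for all 5. An effect of the extract stays open, as untested beyond the group comparison itself.

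With that component in the model, camera called 7 lists at the preset correlation and 1, proteasome, with an estimated one, which for this list was again too low (-0.0131). Besides the 3 above, the lists called at the preset one were macrophage and Kupffer cell markers (1.11e-04, estimated 0.406) and NRF2 genes (0.0174, estimated 0.115), both higher in MSXH. Gluconeogenesis (7.80e-04, estimated 0.255) was lower, but higher under both scalings of all arrays, and without MSXH 4 and 6 it was lower when centred (0.0276) and under quantile normalization (0.928). The urea cycle list (8.49e-04, estimated 0.214) was lower with the component, but higher in the values as they stand and under both scalings of all arrays. It was higher without MSXH 4 and 6 when centred (0.338) and lower under quantile normalization (0.836).

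For genes, 0 passed an adjusted p of 0.05, a count that any split reaches (100 of 100, highest other 1), so the splits say nothing on chance there. At an adjusted p of 0.10 the real split gave 12 genes, and 1 of 100 splits, the real one, gave as many (highest other 5). At an unadjusted p of 0.05 it gave 1982, and 3 of 100 splits gave as many (highest other 2336), so that fewer than 5 of 100 splits reached either count in the values as they stand. The splits were not repeated under the scalings, where the counts were 0 under an adjusted p of 0.10 and 748 (quantile) or 210 (centred) at an unadjusted p of 0.05, under the 909.65 expected. The counts at an unadjusted p of 0.05 without MSXH 4 and 6 were 1873 as the values stand, 2118 with quantile normalization and 357 centred, and those under an adjusted p of 0.10 were 9, 0 and 1. The counts thus depend on the scale and on these 2 arrays.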

How the results depend on the processing

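Leaving out MSXH 4 and 6, alone, with a scaling or with an estimated correlation, the t test, the most variable probe set, the standardized list level and all but the first null of the rank product were chosen only after the data were seen.

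The count of 0 genes by limma stayed 0 under quantile normalization, centring, genes above the median gene, block, all probe sets, eBayes without trend and with a robust trend, array weights, without MSXH 4 and 6, alone and with each scaling, and with the most variable probe set, with unadjusted counts from 210 (centred) and 748 (quantile) to 2118, and 4816 over 45037 probe sets. Asking for a fold of 1.2 besides could only give 0 again. The count was 12 at an adjusted p of 0.10, 1 with the mean of a gene's probe sets (Tnfrsf22, adjusted p 0.0449), 4 by rank sum, 3 by t test, and 5831, 1183 and 951 by rank product with the first null, the second, and the second without MSXH 4 and 6. The null from splits gave 0. Leaving out 1 array gave 0 to 3 genes: 3 without HFD 3 (Fam149b, Prokr1, Tor4a), 1 (Prokr1) without HFD 6 and without HFD 9, 1 (Zfp467) without MSXH 2 and 1 (Fam149b) without MSXH 3. The 12 genes under an adjusted p of 0.10 became 0 under both scalings and with the block, 9 without MSXH 4 and 6, and 1 and 0 when centring and quantile normalization were added. Leaving out 1 array gave 0 to 22: 0 without HFD 2, HFD 10, MSXH 1, MSXH 5, MSXH 7 or MSXH 8, 1 without MSXH 3, 2 without HFD 6, 4 without HFD 9, 5 without HFD 7, 6 without HFD 4, HFD 8 or MSXH 4, 7 without MSXH 6, and 22 without HFD 3 or HFD 5. The cause was not tested.

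The 5 lists became 19 under each scaling (18 higher and 1 lower with quantile normalization, 19 higher and 0 lower centred), 14 (6 higher, 8 lower) centred without MSXH 4 and 6, 1 with quantile normalization without them, 3 with array weights, 1 with an estimated correlation, with all arrays or without MSXH 4 and 6, and 0 by fry. Leaving out 1 array gave 2 to 6: 2 without HFD 6 or MSXH 8, and 3 without HFD 4, HFD 10, MSXH 6 or MSXH 9. The per-array level called 0, and 1 without HFD 3 or without MSXH 1 (range 0 to 1). The growth hormone list had an adjusted p of 0.0710 with mean probe sets, 0.221 with weights, 0.182 without MSXH 4 and 6, 0.0908 with the most variable probe set, and 0.00645 to 0.290 leaving out 1 array, called in 8 of 20. The ER stress list had 0.0636 with weights and 1.55e-04 to 0.0633, lost without MSXH 8. The proteasome list had 0.0822 centred and 1.91e-06 to 0.0785, lost without HFD 6 and without MSXH 8. The immediate early list had 0.475 under quantile normalization, 0.694 centred, 0.0681 with the block and 0.00468 to 0.212, called in 10 of 20. The interferon list had 5.79e-06 to 0.0629, lost without MSXH 9. With an estimated correlation the adjusted p was 0.838 for interferon, ER stress and growth hormone and 0.786 for immediate early; by fry it was 0.906 for all 5. With an estimated correlation and without MSXH 4 and 6 it was 0.471 for interferon, 0.668 for ER stress, 0.767 for growth hormone and 0.512 for immediate early genes, while proteasome stayed called (0.00233), and triglyceride (0.807) and acute phase (0.807) turned.

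By construction, centring takes off array medians whose SD, 2.51e-04, is 20.8 times that of the median gene, and it moved the median gene by 1.62e-04; quantile normalization moved it by 1.69e-04. The medians of MSXH 4 (6.52255) and MSXH 6 (6.52235) set most of that spread; without them the SD was 2.72 times that of the median gene, and centring turned 0 of the 72 named genes. A direction kept under centring of all arrays by a gene that is lower in MSXH was fixed by this offset and shows nothing more. Under quantile normalization Uqcrq and Ugt2b1 were identical in all arrays and gave no value, and nor did these or Psma3, Herpud1, Rps20 and Sult3a1 without MSXH 4 and 6.

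Standardized differences turned to Aspg -0.475, Fam149b -0.149, Arhgap45 -0.415, Plekhb2 -0.218, Casp9 -0.115, Samd9l -0.469, Stoml1 -0.711 and Oasl1 -0.111 under quantile normalization. There, Tap1 was -0.0432, Irf1 -0.0268, Stat5a -0.397, Gstm4 -0.480, Cidea -0.758, Gcgr -0.250, Cd3d -0.825 and Pmvk -0.166. Itgam was -0.520, Haao -0.243, Cebpa -1.48, Hbb-b2 -0.451, Nr1d1 -0.567, Cel -0.755 and Il1r2 -0.762. Centred, Fam149b was -0.546, Rcor3 -0.294, Thtpa -0.498, Rnf213 -0.408, Cnot6l -0.620, Arhgap45 -0.512, Carhsp1 -0.0946 and Plekhb2 -0.507. Casp9 was -0.494, Samd9l -0.407, Stoml1 -0.587, Tap1 -0.420, Stat5a -0.132, Uqcrq -0.648, Gstm4 -0.271, Cidea -0.617 and Gcgr -0.605. Cd3d was -0.652, Pmvk -0.392, Itgam -0.651, Haao -0.384, Hbb-b2 -0.342, Nr1d1 -0.553, Cel -0.647 and Il1r2 -0.634. With mean probe sets Sync was 0.341, Lrrc49 1.26 and Rps20 0.0666. With the most variable probe set Sync was 0.738, Lrrc49 1.76, Lonrf2 0.303, Uqcrq -2.02e-04, Rps20 0.437 and Ehf 0.140. With quantile normalization and without MSXH 4 and 6, 12 named genes turned: Pimreg 0.909, Stoml1 -0.355, Psma5 and Psmb4 0.422, Ppp1r15a 0.685 and Cidea -0.493. The others were Cd3d -1.13, Haao -0.0484, Cebpa -1.28, Pecam1 0.221, Cel -0.414 and Il1r2 -0.532. The identical value of Psma5 and Psmb4 is what 1 lower HFD array gives when all other arrays tie, so it is not a shift of the group. Over leaving out each array, named genes gave 1434 values on the same side and 6 that newly passed.

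Under quantile normalization the lists that turned had adjusted p values of 0.246 for growth hormone, 0.482 for ER stress, 0.308 for proteasome, 0.274 for mitochondrial oxidation, 0.00386 for PPARA, 0.0108 for cholesterol and 0.00375 for gluconeogenesis. They were 0.347 for female-biased, 0.0109 for acute phase, 0.302 for lymphocyte, 0.0108 for stellate, 0.321 for endothelial, 0.712 for cholangiocyte, 0.829 for adipocyte and 0.689 for erythroid genes. They were 0.503 for neutrophil and for cell cycle, 0.0647 for xenobiotic, 1.34e-05 for heat shock and 0.00136 for ribosomal genes. Centred, they were 0.169 for growth hormone, 0.232 for ER stress, 0.342 for PPARA, 4.28e-05 for cholesterol, 0.0353 for gluconeogenesis, 0.0252 for female-biased and 0.0105 for acute phase genes. They were 2.07e-06 for stellate, 0.239 for cholangiocyte, 0.0449 for adipocyte, 0.767 for erythroid, 1.79e-06 for xenobiotic, 2.92e-08 for heat shock and 0.390 for respiratory chain genes. Above the median gene, triglyceride was 0.859, bile acid 0.677, lipoprotein 0.894, lymphocyte 0.603, NRF2 0.918 and circadian 0.894. With the block, neutrophil was 0.911. With mean probe sets, lipoprotein was 0.913, cholangiocyte 0.961, acinar 0.971 and erythroid 0.951. With weights, triglyceride and cholesterol were 0.872 and urea 0.902. By fry, acute phase, stellate and heat shock were 0.976. Without MSXH 4 and 6, triglyceride and acute phase were 0.771. With the most variable probe set, triglyceride was 0.975, lipoprotein 0.737, cholangiocyte 0.911, acinar 0.967 and erythroid 0.737.

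Centred and without MSXH 4 and 6, the lists that turned had adjusted p values of 0.789 for triglyceride, 0.712 for female-biased, 0.965 for acute phase, 0.849 for erythroid, 0.567 for heat shock and 0.928 for respiratory chain genes. With quantile normalization and without these arrays, the calls of growth hormone (0.651), ER stress (0.401) and immediate early genes (0.401) ended and proteasome turned (0.928). Triglyceride (0.953), cholesterol (0.801), bile acid (0.928), female-biased (0.928), lymphocyte (0.734), endothelial (0.651) and hepatocyte (0.651) genes turned as well. So did erythroid (0.929), neutrophil (0.651), heat shock (0.651), ribosomal (0.696), urea (0.836) and cell cycle (0.734) genes.

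Leaving out 1 array also turned lists that were not called, with adjusted p values of 0.824 to 0.996 for triglyceride, 0.190 to 0.984 for cholesterol, 0.804 to 0.996 for bile acid, 0.754 to 0.993 for lipoprotein and 0.774 to 0.992 for acute phase. They were 0.254 to 0.996 for macrophage, 0.330 to 0.977 for stellate, 0.707 to 0.996 for cholangiocyte, 0.605 to 0.969 for hepatocyte and 0.763 to 0.998 for neutrophil. They were 0.660 to 0.992 for circadian, 0.452 to 0.984 for heat shock, 0.272 to 0.997 for ribosomal and 0.204 to 0.969 for urea genes. For all of these the cause was not tested beyond the construction of the 2 scalings. The number of mice limits what can be seen: on simulated data limma recovered 34% of genes shifted by 2 SD. That share holds for a run with other genes shifted by up to 3 SD and independent noise.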

Other observations

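The correlations with Mt1, the glucocorticoid test and the choice of Eno3 were set only after the levels of these genes had been seen to vary; the list of glucocorticoid targets was written before it was set against Mt1.

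Some liver genes varied widely between mice of both groups. Mt1, a metallothionein that binds zinc, ranged from 8.15 to 10.1 over the 20 mice, with 9.22 ± 0.60 in HFD and 9.35 ± 0.65 in MSXH (SD, n = 10 each). The steroid hydroxylase Cyp17a1 ranged from 8.04 to 8.71 and followed Mt1, with a Pearson r of 0.926 and a Spearman rho of 0.928. Hsd3b5, a male-biased steroid dehydrogenase, ranged from 7.63 to 8.82 and went against Mt1, with r = -0.890 and rho = -0.938. The permutation p was 1e-05 for both genes and both measures, the smallest these permutations can give, and 2e-05 after adjustment over the 6 relations computed. Without the 2 mice farthest from the median of Mt1, r was 0.898 for Cyp17a1 and -0.879 for Hsd3b5. Within HFD and MSXH, r was 0.901 and 0.9503 for Cyp17a1 and -0.854 and -0.926 for Hsd3b5. The group differences of Mt1, Cyp17a1 and Hsd3b5 had adjusted p values of 0.898, 0.818 and 0.870.

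The level of 3 lists was also set against Mt1. For the growth hormone and male-biased genes r was -0.836 and rho -0.911 (permutation p 1e-05, the smallest possible, adjusted 2e-05), with r -0.792 in HFD and -0.878 in MSXH, and -0.834 without the 2 farthest mice. For the ER stress genes r was -0.772 and rho -0.750 (permutation p 7e-05 and 2.2e-04, adjusted 9.6e-05 and 3.3e-04), with r -0.645 in HFD and -0.874 in MSXH, and -0.704 without the 2 farthest mice. For the interferon genes r was -0.591 and rho -0.559 (permutation p 0.00665 and 0.0115, the same after adjustment), with r -0.586 in HFD and -0.751 in MSXH. Without the 2 farthest mice r was -0.388, so that part of this last relation rests on them.

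A candidate explanation for this axis is glucocorticoid signalling that differed between mice. The mean level of 12 glucocorticoid target genes followed Mt1 with r = 0.864 in HFD and 0.825 in MSXH, where under 0.3 in both groups would have argued against it. Over all mice r was 0.780 and rho 0.635 (permutation p 8e-05 and 0.00323, adjusted 9.6e-05 and 0.00388), and r was 0.681 without the 2 farthest mice. Fkbp5, Cebpd, Tat and 8 more, 11 of 12, had r above 0.5 in both groups, as did 6.49% of 18180 genes, and Angptl4 did not (0.417 and -0.0340). Of 10000 random lists of 12 genes, 9 had as high a lower r; no hormone was measured here, and 7 of the 12 genes are also in the fixed lists.

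Eno3, the muscle form of enolase and among the 30 muscle genes, was higher in MSXH in 100 of 100 pairs. Its standardized difference was 0.808 with an adjusted p of 0.527, and 2.99 with an adjusted p of 0.0883 without MSXH 4 and 6. Eno3 was the extreme of the 30 there, and others went both ways: Mylpf stood at 1.86 and Myh1 at 1.40, but Tnnt3 at -1.21 and Ckmt2 at -1.27. Without these arrays the mean level of the 30 genes had a permutation p of 0.0731.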
